A study of Homo sapiens with 20 samples.

How the data were processed

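TPC-1 cells, a line derived from a human papillary thyroid carcinoma, were profiled by RNA-seq and by miRNA-seq after 48 h with polymorphonuclear myeloid-derived suppressor cells (PMN-MDSCs) or without them. Each assay had 6 coculture and 4 control libraries, and the groups were taken from the treatment labels. Per the labels' protocols, total RNA was extracted with Trizol, its quality was checked on a Bioanalyzer, small RNA was purified with a miRNeasy kit, and libraries followed standard Illumina protocols. The mode of coculture, the origin of the PMN-MDSCs and any step that parted them from the TPC-1 cells before lysis are not given in the sources used here.

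The authors deposited raw read counts, 1 table per gene symbol for RNA-seq and 1 per mature miRNA for miRNA-seq, with whole numbers and library totals that differ. Per the submitters' processing notes, HISAT2 2.0.4, BWA and the build GRCh38.p10 were used, with no role assigned to each. The counting tool, the annotation, the miRBase release, trimming and the use of strand are not given in the sources used here. Without a stated strand setting, reads from overlapping or antisense genes cannot be separated, and counts of close paralogs and of miRNAs with near-identical sequences are uncertain. The deposited RNA-seq table held 54261 features, of which 24191 had no count in any library, and the miRNA table held 2656, of which 26 had none. No value column of either table was left unused, so the number of unused columns was 0. Transcript lengths from the RNA-seq table served for a check of length bias alone. Coordinates are those of the deposited RNA-seq table.

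RNA-seq totals ran from 40237801 to 48197608 counts and miRNA-seq totals from 3971608 to 5895539. In RNA-seq, 3 counts, taken as the floor of a library, corresponded to 0.0622 to 0.0746 CPM, the read count scaled to a common library total. In miRNA-seq they corresponded to 0.509 to 0.755 CPM. A gene with 0 counts in all 4 control libraries is given as at least N-fold higher against the mean floor of 3 counts per library, and a gene with 1 to 3 control counts is given as a ratio with its 95% counting interval. Reads carried no stated molecular identifiers, so intervals and floors cover counting error only. Library pairs within a group were compared by a chi-square of their counts over genes. The smallest value was 7.36 per degree of freedom, between RNA-seq controls 3 and 4, so no pair agreed within sampling noise and every library was counted.

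Counts were analysed in R 4.3.3 with edgeR 4.0.16, with TMM normalization, filterByExpr by group, robust glmQLFit and glmQLFTest for coculture minus control, in a separate fit for each assay. This left 15629 genes and 797 miRNAs. Benjamini-Hochberg adjustment ran over all features of an assay, at a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of its F statistic. CPM values use the TMM library sizes and are given as mean ± SD. Gene lists, 32 for mRNA and 10 for miRNA, were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Beside it ran camera with an estimated correlation and fry, whose directional p asks whether the genes of a list move one way on balance and makes no comparison with other genes. List p-values were adjusted over the lists of an assay. A list needed 3 tested members, which left 1 list untested. Of 1053 list entries, 1049 were matched to the tables as members, some under another symbol. Of the other 4, 3 were second names of a member and 1 was not matched. The groups, the tests, the lists, the naming rule and the alternatives were fixed before the data were examined, except where a choice is said to have been made after seeing the data.

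The naming rule took, among genes past the threshold with a mean CPM of at least 5 (miRNA: 10) in the higher group and no overlap between groups, the 12 largest rises and the 12 largest falls. Clone-type names, pseudogenes, XIST and Y-linked genes were passed over. It added miR-486-3p, miR-486-5p, their host gene ANK1 and NFKB2 whatever their test, up to 4 members of each list by adjusted p, and the 3 most abundant members of each marker list, of which 1 gene is not reported here. Named after their values were seen were S100A9, MIR3142HG, AKR1B1, TMEM132A, COL6A2, miR-146b-3p, miR-223-3p, miR-142-3p, miR-142-5p, miR-200c-3p and miR-141-3p.

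The scripts were tested on simulated negative binomial counts drawn from the means and sizes of these libraries. In the RNA-seq comparison, on 15413 genes, the share of changed genes recovered was 32% at 1.5-fold, 66% at 2-fold, 91.8% at 4-fold and 98% at 8-fold. In the miRNA comparison, on 769 miRNAs, it was 30.6%, 78.7%, 100% and 100%. Of unchanged features, 4 of 15215 genes and 3 of 584 miRNAs were called. A list shifted 1.5-fold ranked 1 among 31 mRNA lists and 1 among 10 miRNA lists, with 0 other lists called. In a first version of that test the shifted miRNA list shared a draw with the single changed miRNAs and was not recovered, after which the list was given a draw of its own. Features were drawn independently of each other, with no structure between libraries. The 0 other lists called therefore do not test list calls where genes are correlated.

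Alternatives were RLE, upper quartile and plain library-size scaling, no filter, a filter of at least 1 CPM (miRNA: 10) in at least 4 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, robust fitting switched off, and leaving out each library in turn. Numbers 5 and 6 occur in coculture alone, so with the block these libraries take no part in estimating the contrast. Settings added after seeing the data left out RNA-seq coculture libraries 1 and 2, kept numbers 1 to 4 alone with 1 and 2 against 3 and 4 as a batch term, or used coculture 1, 2 and 5 and control 1 against the other 6 libraries as a batch term. Refits on 100 of the 210 splits of 10 libraries into 6 and 4 counted how often other groupings gave as many calls. Correlations across libraries used exact permutations in Python 3.11.15 with SciPy 1.17.1. A planned search for miR-486-3p seed sites in 3' UTRs was not run, since no genome with 3' UTRs was used here.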

Results

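Gene expression and mature miRNAs were measured in TPC-1 cells, a human papillary thyroid cancer line, after 48 h with PMN-MDSCs, immature neutrophil-like myeloid cells that restrain T cells and gather in tumors. There were 6 coculture and 4 untreated control libraries per assay. Totals were 40237801 to 48197608 counts in RNA-seq and 3971608 to 5895539 in miRNA-seq. No gene took more than 1.11% of an RNA-seq library, while miR-21-5p, an abundant miRNA of carcinoma cells, took 38.6% to 43.2% of each miRNA library. Nothing in the labels states that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. On the first principal component of the RNA-seq values (39.3% of the variance), coculture libraries 1 and 2 lay at -66.1 and -60.6, and the other 8 libraries between 0.908 and 31.8. The second component (22.8%) held the controls at 18.9 to 32.2, coculture 1 and 2 at 4.98 and 8.62, and coculture 3 to 6 at -38.9 to -16.8.

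The RNA-seq comparison asked which genes of the TPC-1 libraries differed after 48 h with PMN-MDSCs. CCL24, a chemokine for eosinophils, was at 13.4 ± 4.69 CPM (SD, n = 6) against 0.0275 ± 0.0403 (n = 4), a log2 fold change of 8.73 ± 0.54 (SE), and CHI3L1, a secreted chitinase-like glycoprotein, was at 15.2 ± 9.95 against 0.0535 ± 0.0326 CPM. Among genes that the controls expressed well, CXCL8, which draws neutrophils, rose from 20.4 ± 1.49 to 302 ± 185 CPM, and C3, the central complement component, from 9.33 ± 4.45 to 119 ± 59.7. Of 15629 genes tested with edgeR, 178 were higher and 29 lower in coculture at an adjusted p under 0.05. At least 2-fold differences held for 148 of the higher and 8 of the lower genes. Controls had a mean under 0.5 CPM for 87 of the higher genes, 0.5 to 5 CPM for 33 and 5 CPM or more for 58. Ranges without overlap between the groups occurred for 3.62% of all genes, where chance gives 0.952%. The count of higher genes was 114 without control 3 and 112 without control 4.

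The other largest rises by the naming rule were LYZ, the lysozyme of myeloid cells (log2 fold change 7.28 ± 0.35), CYBB, the catalytic subunit of the phagocyte oxidase (6.22 ± 0.50), and IL1B, the inflammatory cytokine interleukin 1 beta (5.96 ± 0.52). CYP27A1, the mitochondrial sterol 27-hydroxylase, rose by 4.95 ± 0.49, CSF3, the granulocyte growth factor, by 4.84 ± 0.68, and KCCAT211, a long noncoding RNA, by 4.10 ± 0.69. ELF3, an epithelial ETS transcription factor that NF-kB induces, rose by 4.07 ± 0.76, CYP1B1, a cytochrome P450 under the aryl hydrocarbon receptor, by 3.84 ± 0.47, and C3 by 3.68 ± 0.47. Adjusted p-values from edgeR over these 12 genes, CCL24, CHI3L1 and CXCL8 included, ran from 8.38e-07 for LYZ to 0.0174 for ELF3. For ELF3 it was up to 0.0911 on leaving out control 1, 3 or 4, 0.144 with no filter and 0.164 with limma-voom. For KCCAT211 it was 0.0517 without control 1 and 0.0931 with no filter, and for CSF3 0.0801 with limma-voom. Both calls were also lost without coculture 1 and 2, an alternative chosen after seeing the data. Singled out after their values were seen, AKR1B1, the aldose reductase, rose from 663 ± 122 to 1970 ± 456 CPM (edgeR adjusted p = 0.000874), and TMEM132A, a membrane protein gene, from 55.8 ± 4.36 to 154 ± 27.2 (edgeR adjusted p = 0.000197).

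**Figure D1:**
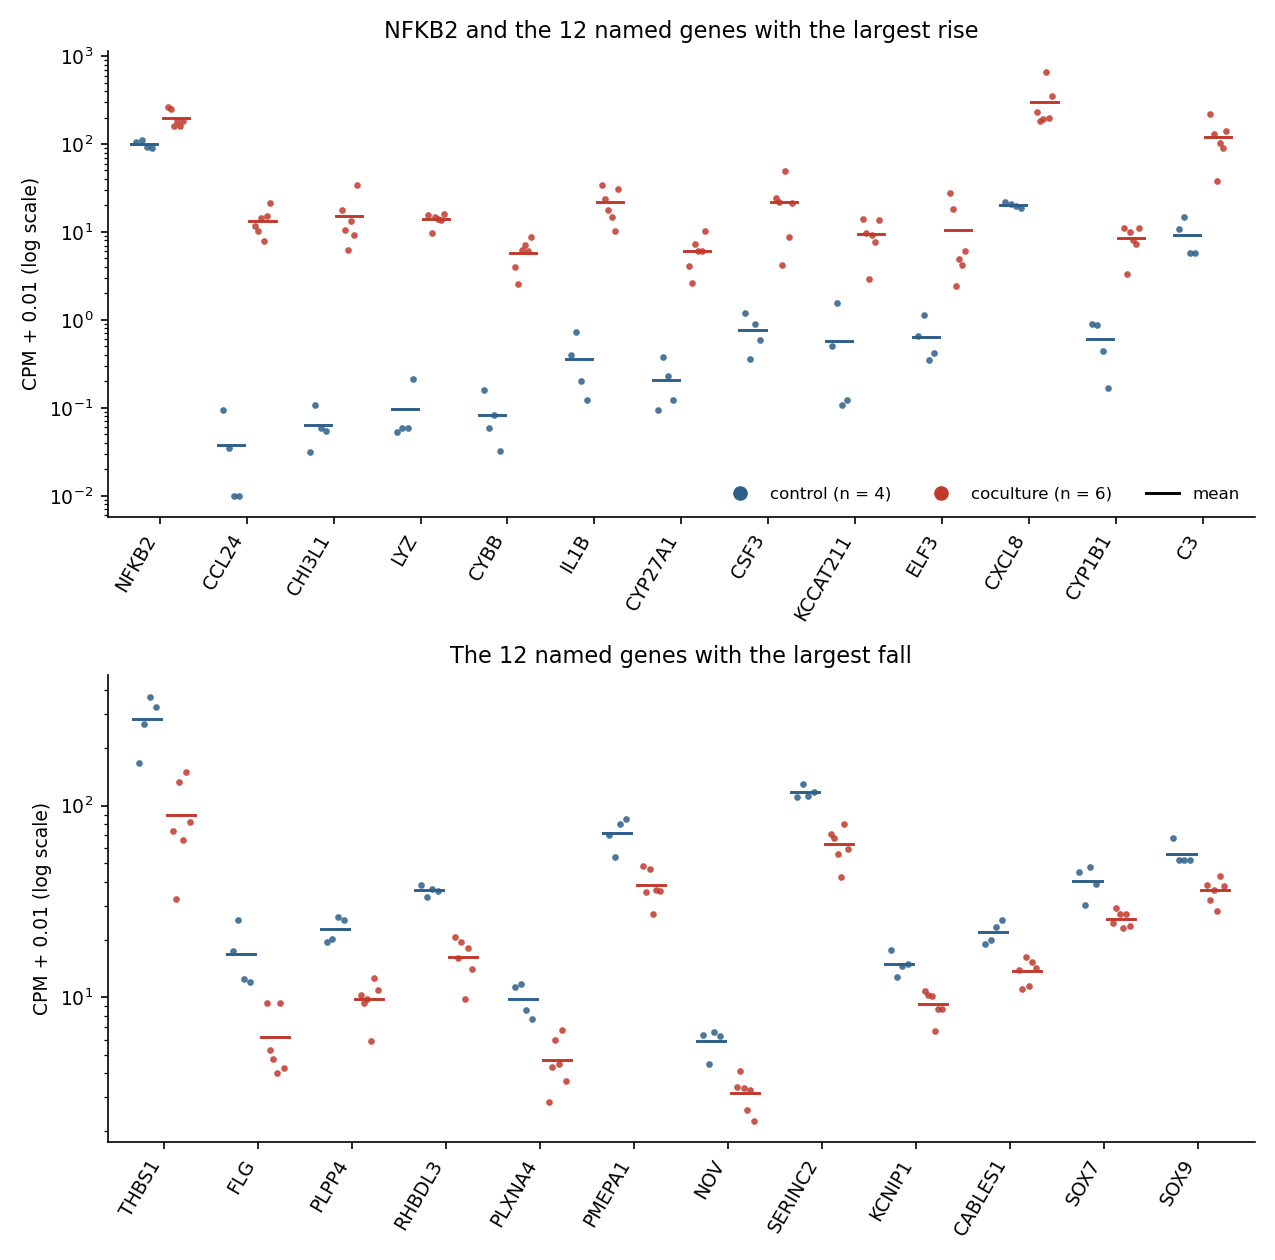
CPM plus 0.01, on log axes, in each control (n = 4) and coculture (n = 6) RNA-seq library, with lines at the group means, for NFKB2 with the 12 named genes of largest rise and for the 12 of largest fall. CXCL8 lay between 185 and 660 CPM in coculture and between 18.7 and 22.1 CPM in controls, and no named gene of either panel had overlapping groups.

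Members and targets of the NF-kB pathway, the transcription factor family that drives inflammatory genes, were higher in coculture for many of the genes tested. RELB, the partner of p52 in the noncanonical pathway, rose from 43.6 ± 5.63 to 99.3 ± 7.42 CPM (log2 fold change 1.19 ± 0.10). BIRC3, an NF-kB target that restrains cell death, rose by 1.63 ± 0.18, SOD2, the mitochondrial superoxide dismutase, by 1.97 ± 0.23 from 149 ± 21.2 to 585 ± 185 CPM, and IL6, a cytokine that signals through STAT3, by 2.40 ± 0.31, a call that the replicate block ended (adjusted p = 0.0758). Of 33 tested members, 18 were higher, 0 lower and 15 not called, and adjusted over the list alone 25 were higher and 1 was lower. That member, singled out after its value was seen, was MAP3K14, the kinase NIK of the noncanonical pathway, at -0.49 ± 0.11 (edgeR adjusted p = 0.0598 over all genes). Secreted cytokines and chemokines rose too, with 12 of 20 tested genes higher, 0 lower and 8 not called, and 13 higher and 1 lower adjusted over the list alone. The lower 1, named after its value was seen, was TGFB2, a transforming growth factor, at -0.68 ± 0.23 (edgeR adjusted p = 0.287 over all genes). CXCL5, another chemokine for neutrophils, had 1 count over the 4 controls and 1147 over the coculture libraries, a ratio of 767 (95% counting interval 137 to 30330). The camera adjusted p was 1.54e-47 for the NF-kB list and 1.64e-34 for the cytokine list, and with an estimated correlation the adjusted p was 0.0011 and 0.00034. Several genes, CXCL8 and IL6 among them, stand on both lists, so the results of the lists are not independent. LYZ was at 13.9 ± 2.17 CPM in the coculture libraries against 0.086 ± 0.0783 in the controls.

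NFKB2, which encodes the p100 precursor of the NF-kB subunit p52 and which has been proposed as a target of miR-486-3p, was about 2-fold higher in coculture. Its level was 199 ± 45.8 CPM in coculture (n = 6) and 99.4 ± 10 CPM in controls (n = 4), a log2 fold change of 1.004 ± 0.16 with an edgeR adjusted p of 0.00548. Each coculture library lay above each control. In the deposited table the gene lies on chromosome 10 from 102394110 to 102402529 on the plus strand, where the build per the submitters' processing notes is GRCh38.p10. Leaving out any single library gave 0.91 to 1.06, with edgeR adjusted p-values up to 0.0354.

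Several genes of myeloid and other white blood cells that had few or no counts in the controls were present at low levels in coculture. CD53, a leukocyte tetraspanin, had 0 counts in the 4 controls and 1.68 ± 0.557 CPM in coculture, at least 24.1-fold higher. By the same bound TYROBP, a signaling adaptor of myeloid cells, was at least 17-fold higher, CD52, a leukocyte surface peptide, at least 10.4-fold and MRC1, the macrophage mannose receptor, at least 7.28-fold. ITGAM, the CD11b chain by which PMN-MDSCs are recognised, had 3 control counts and a ratio of 66.2 (95% counting interval 22.4 to 323). S100A9, an abundant protein of neutrophils singled out after its value was seen, had 1 control count and a ratio of 157 (27.9 to 6235). CD14, a monocyte receptor for lipopolysaccharide, rose from 0.0863 ± 0.0435 to 2.9 ± 1.22 CPM, CSF1R, the receptor for macrophage growth factor, from 0.511 ± 0.27 to 2.75 ± 0.866, and ITGB2, the beta chain of leukocyte integrins, from 1.5 ± 0.263 to 11.2 ± 2.53. PTPN6, a phosphatase of blood cells, rose by 5.39 ± 0.56 on the log2 scale. The replicate block ended the calls of TYROBP, CD52, MRC1 and CSF1R, with adjusted p of 0.0615, 0.0821, 0.116 and 0.131.

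Of 13 tested neutrophil and PMN-MDSC markers, 8 were higher, 0 lower and 5 not called, with the same numbers adjusted over the list alone (camera adjusted p = 1.47e-55). Of 12 monocyte and macrophage markers, 7 were higher, 0 lower and 5 not called, and adjusted over the list alone 10 were higher and 1 was lower (camera adjusted p = 1.4e-22). That 1 was VCAN, a matrix proteoglycan, at 90.8 ± 22.7 CPM against 151 ± 43 (edgeR adjusted p = 0.169 over all genes). Of 18 pan-leukocyte genes, 12 were higher, 0 lower and 6 not called, with the same numbers adjusted over the list alone (camera adjusted p = 1.55e-47). With an estimated correlation the adjusted p of these 3 lists was 0.000184, 0.00034 and 0.0011. The full lists held 40, 28 and 22 members, and those with too few counts were not tested. A marker nearly absent from the controls passed the count filter only through its coculture counts, so it could hardly be called lower. Called genes with a control mean under 1 CPM numbered 7, 7 and 9. The numbers called and the list tests are therefore not independent of that filter. The control TPC-1 cells themselves expressed, at 1 CPM or more, 4 of the 13, 4 of the 12 and 7 of the 18 tested genes, and 1 gene of each list stood on another list. The most abundant members were such genes of the TPC-1 cells. G0S2, a lipolysis inhibitor, was at 2930 ± 974 CPM against 2259 ± 227, and RAC2, a small GTPase of blood cells, at 215 ± 61.2 against 172 ± 15.1. SRGN, a proteoglycan of secretory granules, was at 167 ± 23.4 against 148 ± 2.09, LAPTM5, a lysosomal protein of blood cells, at 141 ± 16.3 against 142 ± 9.94, and CD68, a lysosomal protein of macrophages, at 120 ± 31 against 89.1 ± 10.1. None of these 5 was called by edgeR, with adjusted p-values from 0.416 to 0.973.

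Of other blood and stromal markers, IL7R, the interleukin 7 receptor, was called. It was the 1 tested gene among 25 T and NK cell markers, too few for a list test, and rose by 2.18 ± 0.45 on the log2 scale (edgeR adjusted p = 0.0353). The adjusted p was up to 0.129 when coculture 4, 5 or 6 or any 1 of the 4 controls was left out, and the call was also lost with limma-voom, the replicate block and numbers 1 to 4 with a batch term, with adjusted p up to 0.264. B and plasma cell markers had 4 tested members, erythroid genes 3, platelet genes 3 and fibroblast and endothelial markers 6, with 0 called in each, also adjusted over the list alone, and camera adjusted p-values of 0.265, 0.265, 0.603 and 0.502. Controls expressed 3 of the tested genes of each of these 4 lists at 1 CPM or more. PAX5, a B cell transcription factor, was at 6.82 ± 2.37 CPM against 9.03 ± 1.52, BANK1, a B cell adaptor, at 1.6 ± 0.102 against 1.53 ± 0.41, and TNFRSF13C, the BAFF receptor, at 0.909 ± 0.19 against 1.04 ± 0.379. TRIM58, an erythroid ubiquitin ligase, was at 45.2 ± 3.88 against 50.1 ± 3.1, and SPARC, a matrix protein also of platelets, at 350 ± 89 against 335 ± 45.9. MYL9, a myosin light chain, was at 51.1 ± 12.9 against 51.2 ± 7.09 and NRGN, a calmodulin-binding protein, at 16.9 ± 1.47 against 14.9 ± 0.17. EGFL7, an endothelial secreted factor, was at 137 ± 34.7 against 116 ± 7.09, COL1A1, a chain of type I collagen, at 14 ± 26 against 2.62 ± 0.927, and LUM, the matrix proteoglycan lumican, at 2.06 ± 2.19 against 1.58 ± 0.445. Coculture 1 held 67 CPM of COL1A1 and 6.35 CPM of LUM, and the other 5 coculture libraries at most 5.73 and 2.38.

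Of 26 tested genes of the type I interferon response, 25 had a positive fold change and few were called. BST2, the antiviral protein tetherin, had 2 control counts and a ratio of 50.8 (95% counting interval 13.8 to 424), and MX1, an antiviral GTPase, rose by 1.15 ± 0.25 on the log2 scale. IFIH1, the sensor of double-stranded RNA, was at 6.45 ± 2.57 CPM against 2.83 ± 0.347, and EPSTI1, another interferon-induced gene, at 1.99 ± 1.15 against 0.629 ± 0.121, neither called over all genes. In the list 2 were higher, 0 lower and 24 not called, and adjusted over the list alone 18 were higher. The same coculture libraries held 13.9 ± 2.17 CPM of the myeloid gene LYZ. The camera adjusted p of 7.67e-14 became an adjusted p of 0.192 with an estimated correlation. For MX1 the edgeR adjusted p of 0.0399 was up to 0.159 on leaving out coculture 1, 2, 3, 4 or 6 or any 1 of the 4 controls, and the call was also lost with limma-voom, with the replicate block and without coculture 1 and 2.

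In antigen presentation, CD74, the invariant chain of class II molecules, had 2 control counts and a ratio of 281 (95% counting interval 77.5 to 2324), and ICAM1, an adhesion molecule for leukocytes, rose from 51.9 ± 9.34 to 229 ± 90.3 CPM. HLA-B, a class I heavy chain, was at 32.2 ± 15.3 CPM against 12.6 ± 0.74 (edgeR adjusted p = 0.0646), and HLA-DRA, a class II chain, at 0.702 ± 0.774 CPM with 1 control count (edgeR adjusted p = 0.0627). Of 18 tested genes of this list, 2 were higher, 0 lower and 16 not called, and 9 were higher adjusted over the list alone (camera adjusted p = 1.05e-11; adjusted p = 0.0497 with an estimated correlation). JAK-STAT3 targets had 0 of 19 members called and 7 higher adjusted over the list alone, among them CEBPB, an acute-phase transcription factor, at 140 ± 17.4 CPM against 104 ± 9.97. Their camera adjusted p of 8.06e-06 became an adjusted p of 0.117 with an estimated correlation. CD53, a leukocyte gene, had 0 control counts and 1.68 CPM in the same coculture libraries. ICAM1 stands on the NF-kB and papillary thyroid cancer lists as well.

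Among matrix proteases and their inhibitors, MMP9, the gelatinase of neutrophils and many tumors, rose from 1.21 ± 0.378 to 15.5 ± 4.92 CPM, and MMP1, the interstitial collagenase, from 11.7 ± 0.599 to 40.8 ± 18.2. CTSS, a cathepsin of antigen-presenting cells, rose by 4.35 ± 0.42 and SERPINB2, an inhibitor of urokinase, by 4.54 ± 0.78 on the log2 scale. These 4 of 28 tested members were higher, 0 lower and 24 not called, and adjusted over the list alone 7 were higher and 1, MMP16, a membrane-bound metalloprotease named after its value was seen, was lower at -0.60 ± 0.17 (edgeR adjusted p = 0.172 over all genes). The camera adjusted p was 5.82e-07, and the adjusted p with an estimated correlation was 0.0497. MMP9 also stands on the neutrophil list, and ITGB2 of the leukocyte list rose in the same libraries by 2.90 ± 0.21. The call of SERPINB2 (edgeR adjusted p = 0.0107) was lost without control 3 or control 4 (adjusted p up to 0.0576), and also with no filter, limma-voom and the replicate block (up to 0.157).

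COL6A1, a chain of the matrix collagen VI, rose from 248 ± 31.4 to 605 ± 102 CPM, and COL6A2, its partner chain named after its value was seen, from 183 ± 11.5 to 354 ± 79.2. THBS1, the matrix glycoprotein thrombospondin 1, fell from 283 ± 88.5 to 89.8 ± 44.1 CPM. COL6A1 and THBS1 were the 1 higher and 1 lower of 26 tested mesenchymal genes, with 24 not called and the same numbers adjusted over the list alone (camera adjusted p = 0.545). CLDN1, a tight junction claudin abundant in papillary thyroid cancer, rose from 175 ± 27.3 to 338 ± 58.1 CPM as the 1 higher of 18 epithelial junction and keratin genes, with 0 lower and 17 not called, also adjusted over the list alone (camera adjusted p = 0.0757). Of 26 papillary thyroid cancer genes, 2 were higher, CHI3L1 and ICAM1, 0 lower and 24 not called, and adjusted over the list alone 4 were higher and 1 lower. The lower 1, named after its value was seen, was CCND1, the G1 cyclin D1, at -0.29 ± 0.08 (edgeR adjusted p = 0.163 over all genes). Their camera adjusted p of 0.00208 became an adjusted p of 0.352 with an estimated correlation, and without coculture 1 and 2 it was 0.386 at the preset correlation. The replicate block ended the calls of THBS1, COL6A2 (adjusted p = 0.0662) and CLDN1 (0.0781). Thyroid differentiation genes had 0 of 10 tested members called, also adjusted over the list alone (camera adjusted p = 0.162).

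**Figure D2:**
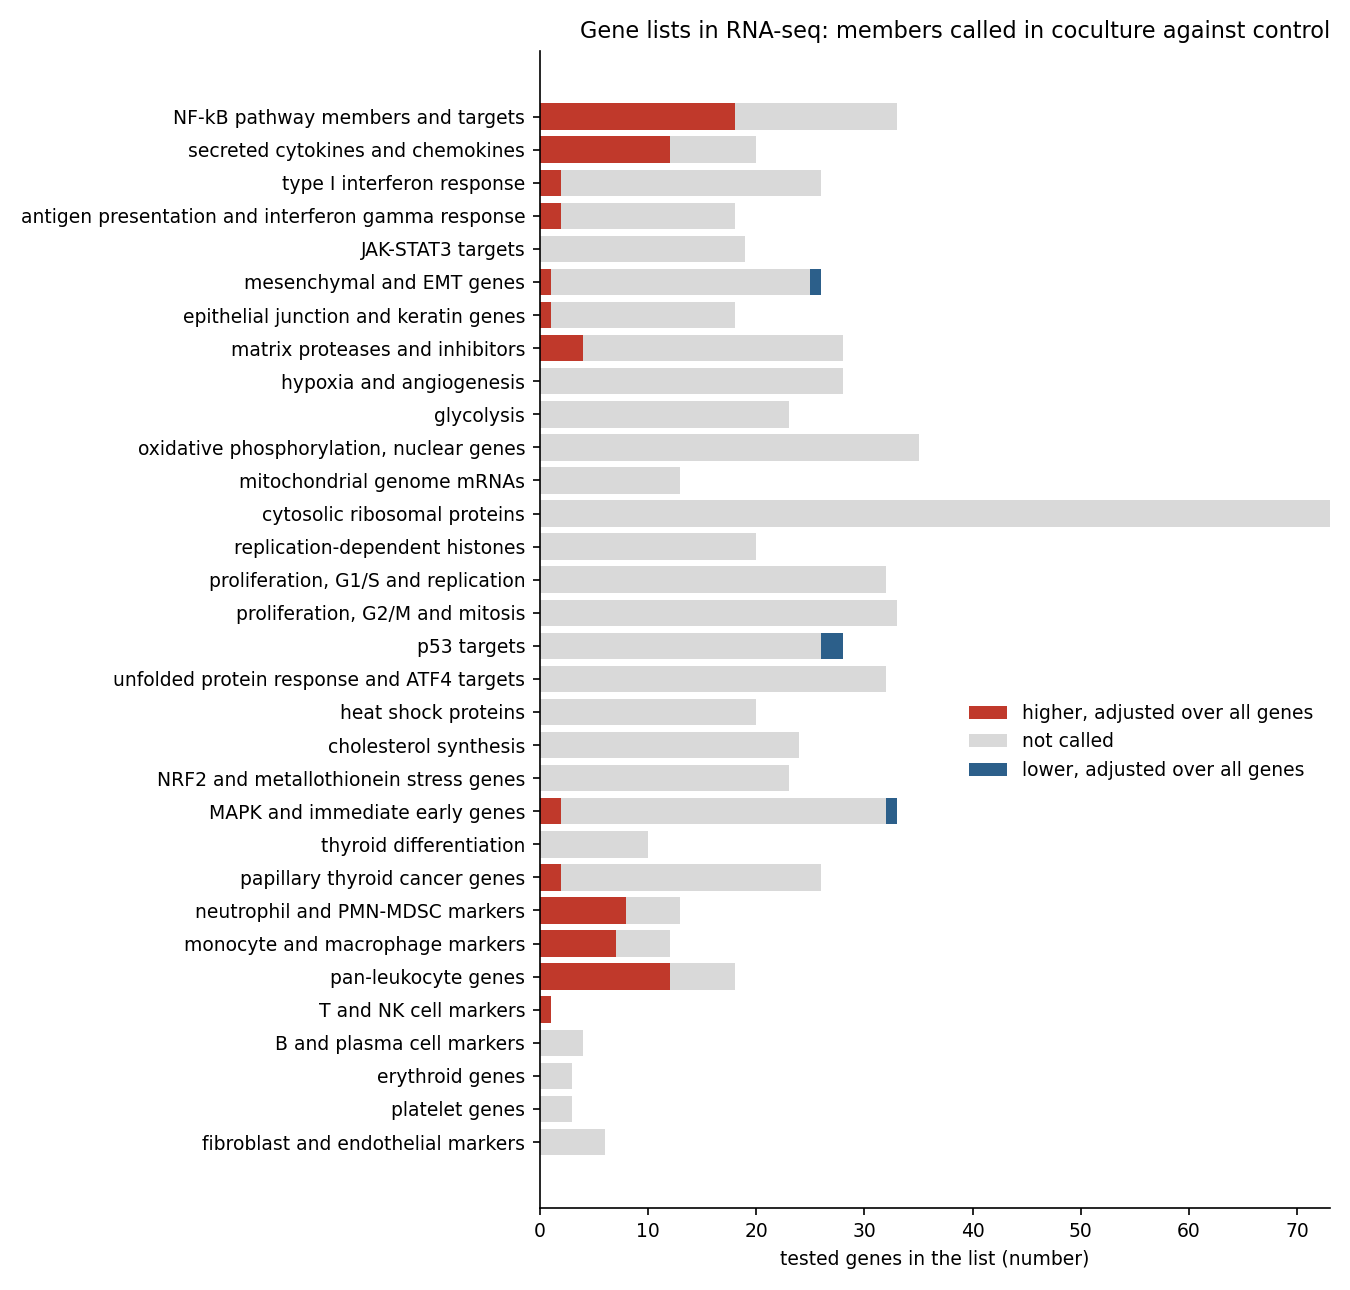
Bars give the number of tested genes of each mRNA list, split into genes called higher, not called and called lower in coculture, adjusted over all genes. The NF-kB list holds 18 higher genes of 33, the neutrophil and PMN-MDSC list 8 of 13 and the p53 list 2 lower genes of 28.

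Genes lower in coculture were fewer and changed less. THBS1 fell the most among named genes, by 1.66 ± 0.35 on the log2 scale, followed by FLG, the epidermal protein filaggrin, by 1.45 ± 0.29, PLPP4, a lipid phosphatase, by 1.21 ± 0.18, and RHBDL3, a rhomboid-type membrane protein, by 1.15 ± 0.17. PLXNA4, a semaphorin receptor, fell by 1.07 ± 0.23, PMEPA1, an inducible brake on TGF-beta signaling, by 0.92 ± 0.16, NOV, a matricellular CCN protein, by 0.90 ± 0.18, and SERINC2, a membrane protein, by 0.90 ± 0.15. KCNIP1, a subunit of potassium channels, fell by 0.70 ± 0.15, CABLES1, a partner of cyclin-dependent kinases, by 0.67 ± 0.13, and the transcription factors SOX7 and SOX9 by 0.66 ± 0.13 and 0.63 ± 0.13. In edgeR the adjusted p of the 12 ran from 0.00357 for PLPP4 to 0.0399 for PLXNA4. PLPP4, RHBDL3 and SERINC2 stayed called whichever single library was left out, but the replicate block ended the calls of PLPP4 (adjusted p = 0.0518) and RHBDL3 (0.0569), so of the 3 only SERINC2 was called in all 22 settings. The other 9 lost their call on leaving out some single libraries, with edgeR adjusted p up to 0.151, for THBS1. PMEPA1 lost it without control 3 or 4, THBS1 without coculture 1, 4 or 6 or control 2, 3 or 4, and FLG without coculture 2, 3, 4 or 6 or control 1 or 2. For PLXNA4 the libraries were coculture 2, 4 and 6 and controls 1 to 4, for NOV coculture 4, 5 and 6 and controls 1, 3 and 4, and for KCNIP1 coculture 5 and 6 and controls 1, 3 and 4. For CABLES1 they were coculture 4 and 6 and controls 2, 3 and 4, for SOX7 coculture 4 and 6 and controls 1, 3 and 4, and for SOX9 coculture 6 and controls 1 to 4. The block also ended the calls of THBS1, PLXNA4, PMEPA1, NOV, KCNIP1, CABLES1 and SOX7, with adjusted p up to 0.225, for NOV. Fits with no filter ended those of THBS1 (0.234) and FLG, the strict filter that of PLXNA4 and upper quartile scaling that of KCNIP1. Numbers 1 to 4 with a batch term ended those of PMEPA1, NOV, KCNIP1 and SOX7, and THBS1 was lost without coculture 1 and 2 and with coculture 1, 2 and 5 and control 1 as a batch term. The count of lower genes was 19 without coculture 2, 12 without coculture 4, 6 without coculture 6, and 13, 18, 5 and 4 without controls 1 to 4. Without coculture 1 and 2, an alternative chosen after seeing the data, it was 112.

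Targets of p53, the tumor suppressor that halts damaged cells, had a positive fold change for 6 of 28 tested members. SESN1, a stress-induced inhibitor of mTORC1, was at 13.3 ± 1.33 CPM against 20 ± 1.72 (edgeR adjusted p = 0.014), and BTG2, an antiproliferative gene that also answers to growth factors, at 23.7 ± 3.52 against 35.5 ± 3.87 (edgeR adjusted p = 0.042). They were the 2 lower members, with 0 higher and 26 not called, and adjusted over the list alone 3 were lower, with POLH, a translesion DNA polymerase named after its value was seen, at -0.46 ± 0.13 (edgeR adjusted p = 0.159 over all genes). The camera adjusted p of 1.16e-06 became an adjusted p of 0.151 with an estimated correlation. SESN1 lost its call without control 1, 3 or 4 (adjusted p up to 0.0609), and BTG2 without coculture 1, 2, 3, 4 or 6 or control 1, 3 or 4 (up to 0.151). The replicate block ended both calls, with 0.145 for SESN1, and upper quartile scaling and the strict filter that of BTG2.

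MAPK and immediate early genes, which growth signals switch on within minutes, went both ways. DUSP1, a phosphatase that turns MAP kinases off, rose from 26.6 ± 1.34 to 41.5 ± 5.41 CPM and EGR2, a zinc finger transcription factor, from 0.17 ± 0.214 to 1.66 ± 0.695, while BTG2 fell. Of 33 tested members 2 were higher, 1 lower and 30 not called, and adjusted over the list alone 8 were higher and 2 lower, BTG2 and CCND1 at -0.29 ± 0.08. The camera adjusted p of 0.00208 became an adjusted p of 0.328 with an estimated correlation and was 0.108 at the preset one without coculture 1 and 2. DUSP1 (edgeR adjusted p = 0.00918) reached 0.0513 without control 4, and EGR2 (0.0184) was lost without control 2, 3 or 4, with adjusted p up to 0.0868. The replicate block ended both calls, with adjusted p of 0.118 and 0.139, and numbers 1 to 4 with a batch term that of EGR2.

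Growth and metabolic groups held no called gene, and several of their list tests moved with coculture 1 and 2, the libraries that stood apart on the first component. Hypoxia and angiogenesis genes had a median log2 fold change of 0.36 over 28 members, with VEGFA, the vascular growth factor, at 112 ± 38.6 CPM against 69.3 ± 11.2 (edgeR adjusted p = 0.282). Their camera adjusted p was 0.00131, the adjusted p with an estimated correlation 0.432, and without coculture 1 and 2 the median was -0.01 with an adjusted p of 0.947. The 32 genes of G1/S and replication had a median of -0.12 (camera adjusted p = 0.000343; adjusted p = 0.449 with an estimated correlation; 0.304 without the 2 libraries). For the 33 genes of G2/M and mitosis the median was -0.08 (camera adjusted p = 0.0432; adjusted p = 0.716 with an estimated correlation), and it was 0.03 without the 2 libraries (adjusted p = 0.623). The 20 replication-dependent histones had a median of -0.17, with adjusted p-values of 0.0373 by camera, 0.192 with an estimated correlation and 0.177 without the 2 libraries. Cytosolic ribosomal protein genes, 73 in number, had a median of 0.08, with adjusted p-values in the same order of 0.0138, 0.716 and 0.522. For 20 heat shock proteins the median was -0.16 and the 3 adjusted p-values were 0.00398, 0.462 and 0.522. Cholesterol synthesis genes, 24 in number, had a median of 0.16 and adjusted p-values of 0.00513, 0.521 and 0.095. Leaving out 1 library moved medians of all 7 lists by over 1.5 times. Without coculture 1 the median was -0.05 for G1/S, -0.04 for G2/M, -0.09 for heat shock proteins and -0.29 for histones, and without coculture 2 it was 0.21 for hypoxia, 0.05 for ribosomal proteins, -0.11 for heat shock proteins and -0.26 for histones. Heat shock proteins were at -0.26 without coculture 3 and -0.27 without coculture 4. Without control 1 ribosomal proteins were at 0.03 and histones at -0.36, without control 2 at 0.05 and -0.29 with cholesterol synthesis at 0.32, and without control 3 cholesterol synthesis was at 0.09. Without control 4 ribosomal proteins were at 0.14, G2/M at -0.05 and heat shock proteins at -0.11. Adjusted over each list alone, 0 genes of these 7 lists were called. Leaving out 1 library ended the camera call of the ribosomal list (coculture 2, control 1 or control 2; adjusted p up to 0.816), the cholesterol list (control 3 or 4; up to 0.171), the histones (coculture 1, 3 or 4, control 2 or 4; up to 0.0782) and the G2/M list (coculture 1, 2 or 5, control 3 or 4; up to 0.555).

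The remaining lists did not pass camera and held 0 called genes. Glycolysis genes, 23 tested, had an adjusted p of 0.265, 35 nuclear genes of oxidative phosphorylation 0.617, and 13 mRNAs of the mitochondrial genome 0.603, with 0 called adjusted over each list alone. For 32 genes of the unfolded protein response and ATF4 the camera adjusted p was 0.56, and adjusted over the list alone 2 were higher, CEBPB and ATF3, a stress-induced transcription factor named after its value was seen, at 0.84 ± 0.21. The 23 genes of the NRF2 and metallothionein stress responses had an adjusted p of 0.265 by camera, a median of -0.07 and a mean of -0.00, with 0 called adjusted over the list alone. In all, 19 of the 31 mRNA lists tested passed camera, 7 passed with an estimated correlation and 10 passed fry.

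The miRNA comparison asked which mature miRNAs differed between the same groups, with miR-486-3p named in the study's title. The miR-146 family, which NF-kB induces and which dampens its signaling, and the miR-200 family, which keeps epithelial cells from a mesenchymal state, were higher in coculture. miR-146a-5p rose from 89 ± 9.46 to 514 ± 230 CPM (log2 fold change 2.53 ± 0.31) and miR-146a-3p from 18.4 ± 2.42 to 101 ± 55.5 (2.45 ± 0.36). miR-146a-5p also stands on the myeloid and lymphocyte lists, and miR-223-3p, a neutrophil miRNA, was at 53.9 CPM in the same libraries, at 3.14 to 3.18 CPM in controls 1 to 3 and at 54 CPM in control 4. miR-146b-5p, abundant in papillary thyroid cancer, rose by 1.33 ± 0.26 and miR-146b-3p, named after its value was seen, by 1.15 ± 0.25. MIR3142HG, the transcript that spans miR-146a on chromosome 5 (160468251 to 160487426, with miR-146a at 160485352 to 160485450) and that was singled out after its value was seen, rose in RNA-seq from 0.672 ± 0.264 to 6.75 ± 2.79 CPM. Of 797 miRNAs tested with edgeR, 9 were higher and 1 lower, with 32 and 59 at an unadjusted p under 0.05. The count of 9 was 5 without coculture 3, coculture 6 or control 1. miR-146b-5p (edgeR adjusted p = 0.0241) was lost without coculture 3 or 6 or control 1, 2 or 4, and miR-146b-3p (0.0426) without coculture 1, 2, 3, 5 or 6 or control 1, 3 or 4, with adjusted p up to 0.156. miR-146b-3p was also lost with upper quartile scaling, library size alone, the replicate block and numbers 1 to 4 with a batch term.

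**Figure D3:**
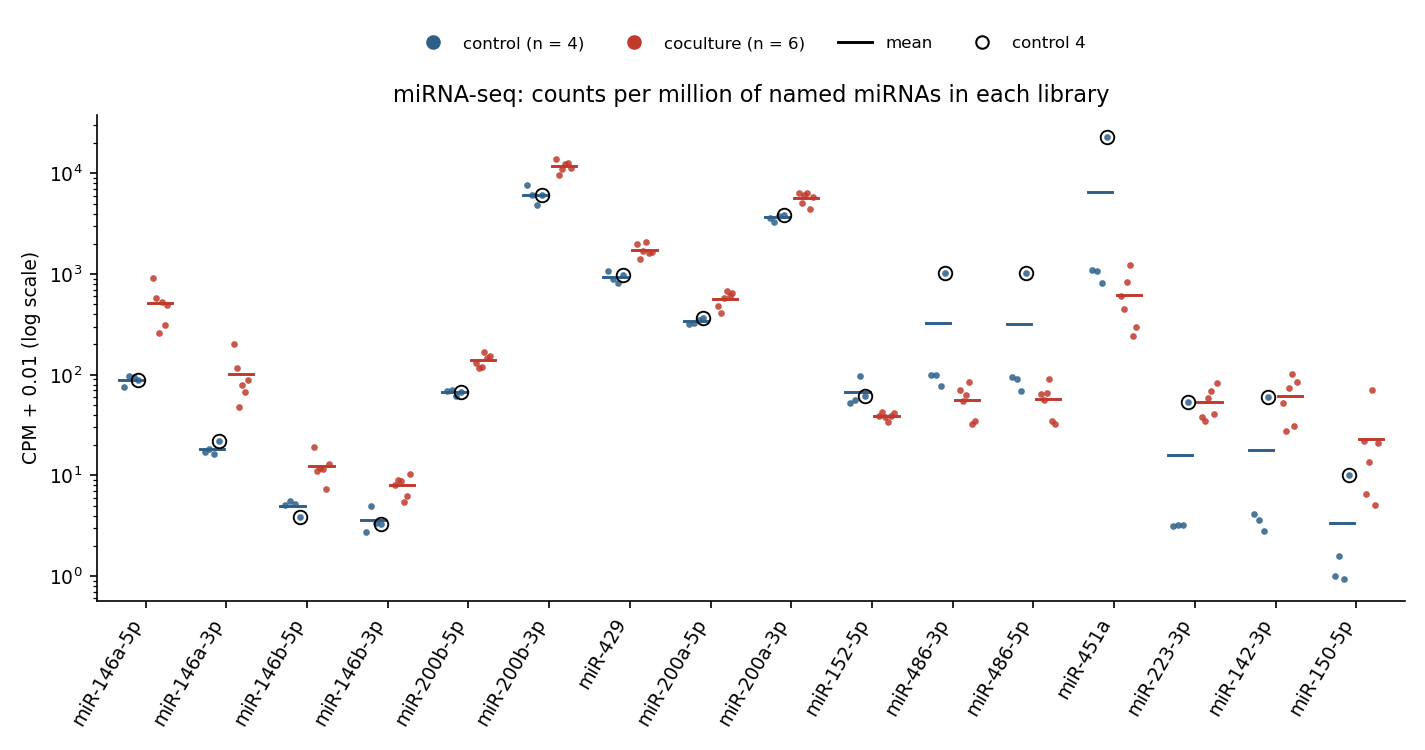
CPM plus 0.01, on a log axis, of named miRNAs in each control (n = 4) and coculture (n = 6) miRNA library, with lines at the group means and a ring around control 4. miR-146a-5p had a mean of 514 CPM in coculture and 89 CPM in controls, and control 4 held 23154 CPM of miR-451a.

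In the miR-200 family, miR-200b-3p rose from 6177 ± 1163 to 11841 ± 1412 CPM (0.94 ± 0.14) and miR-200b-5p by 1.05 ± 0.14. miR-429 rose by 0.90 ± 0.14, miR-200a-5p by 0.74 ± 0.15 and miR-200a-3p by 0.64 ± 0.13. These lie together on chromosome 1 between 1167104 and 1169087. From the cluster on chromosome 12, miR-200c-3p was at 61.1 ± 32.8 CPM against 30.3 ± 9.85 and miR-141-3p at 31.8 ± 15.4 against 14.9 ± 4.15, both named after their values were seen and not called. Of 7 tested family members 5 were higher, 0 lower and 2 not called, and adjusted over the list alone all 7 were higher (camera adjusted p = 2.78e-17; adjusted p = 0.000221 with an estimated correlation). miR-200a-3p and miR-200a-5p (edgeR adjusted p = 0.0241 and 0.0243) reached 0.0788 at most when a library was left out, with calls lost for both without coculture 3, 4 or 6 or control 1 or 2, and for miR-200a-5p also without coculture 5. Scaling by library size alone ended both calls, with adjusted p of 0.0971 and 0.140, and the replicate block that of miR-200a-5p. The 1 lower miRNA, miR-152-5p, was at 39 ± 3.21 CPM against 66.7 ± 20.3 (-0.77 ± 0.17; edgeR adjusted p = 0.0459), and its call was lost on leaving out any 1 library but control 1, with adjusted p up to 0.133, and it was called in 3 of 21 settings.

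miR-486-3p, which is processed from a hairpin within the erythrocyte ankyrin gene ANK1, had lower counts in coculture and was not called. Its level was 56.8 ± 20.4 CPM in coculture (n = 6) against 328 ± 471 CPM in controls (n = 4), a log2 fold change of -2.53 ± 0.76 with an edgeR adjusted p of 0.259. The 4 controls were at 100, 98.8, 78.2 and 1034 CPM, and the 6 coculture libraries between 32.8 and 84.8. Without control 4 the log2 fold change was -0.66 ± 0.27 (edgeR unadjusted p = 0.0304, adjusted p = 0.745). An exact two-sided permutation test of log2 CPM over the 6 coculture libraries and controls 1 to 3 gave an unadjusted p = 0.0476. That permutation test was chosen after the values of control 4 were seen. miR-486-5p, from the same hairpin, was at 57.6 ± 21.8 CPM against 322 ± 473 (edgeR adjusted p = 0.27), and without control 4 its log2 fold change went from -2.48 to -0.53 ± 0.28. The hairpin lies on chromosome 8 at 41660441 to 41660508 on the minus strand, inside ANK1 (41653225 to 41896762), and a second copy is annotated on the opposite strand at 41660444 to 41660507. Both strands of that place can give near-identical miRNAs, so the origin of these counts is uncertain. ANK1 itself was at 4.97 ± 2.15 CPM against 7.33 ± 1.68 (log2 fold change -0.56 ± 0.31; edgeR adjusted p = 0.605).

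Control 4 of the miRNA assay also held more of the miRNAs of red cells and leukocytes. miR-451a, the most abundant miRNA of red cells, was at 23154 CPM there, at 810 to 1091 CPM in controls 1 to 3 and at 243 to 1241 CPM in coculture, and miR-144-3p, from the same red cell cluster, at 273 CPM against 8.42 to 13.2 in the other controls. Over all 4 controls the log2 fold changes were -3.41 ± 1.04 for miR-451a, -3.69 ± 1.06 for miR-144-3p and -3.19 ± 0.96 for miR-144-5p, with edgeR adjusted p-values of 0.235 to 0.259, and without control 4 they were -0.65 ± 0.41, -0.76 ± 0.35 and -0.81 ± 0.41. Of 7 tested erythroid miRNAs, 0 were higher, 0 lower and 7 not called, and adjusted over the list alone 6 were lower. Their camera adjusted p of 0.00519 became an adjusted p of 0.435 with an estimated correlation. Without control 4 the camera adjusted p was 0.0142 and the adjusted p with an estimated correlation 0.415, and the median log2 fold change went from -2.53 to -0.65.

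**Figure D4:**
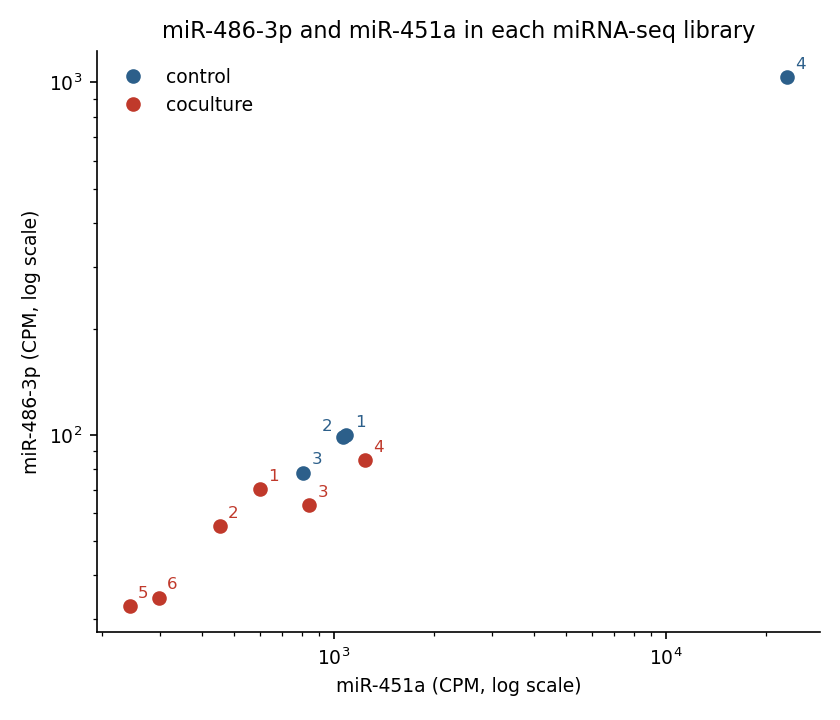
CPM of miR-486-3p against CPM of miR-451a, both on log axes, with 1 point per miRNA library numbered by replicate (6 coculture, 4 control). Control 4 lies at 1034 and 23154 CPM, and the other 9 libraries reach at most 100 and 1241.

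Myeloid miRNAs were also high in control 4. miR-223-3p, a miRNA of neutrophils, was at 53.9 ± 19.1 CPM in coculture, at 54 CPM in control 4 and at 3.14 to 3.18 CPM in controls 1 to 3, and miR-142-5p, of all blood cells, at 97.1 ± 55.4, 464 and 18.9 to 22.9 CPM. miR-223-5p had a log2 fold change of 2.59 ± 0.64 (edgeR adjusted p = 0.0846). Without control 4, edgeR called 12 miRNAs higher and 0 lower of 834, with 32 and 18 at an unadjusted p under 0.05. Among them were miR-223-3p at 4.12 ± 0.36, miR-223-5p at 5.21 ± 0.52, miR-142-3p at 4.18 ± 0.49, miR-142-5p at 2.27 ± 0.44 and miR-150-5p, a lymphocyte miRNA, at 4.32 ± 0.95. miR-223-3p, miR-142-3p and miR-142-5p were named after their values were seen, and with all libraries miR-142-5p was at -0.44 ± 0.97. Of 11 tested neutrophil and myeloid miRNAs, 1, miR-146a-5p, was higher, 0 lower and 10 not called, and adjusted over the list alone 2 were higher (camera adjusted p = 9.63e-05; adjusted p = 0.208 with an estimated correlation). Without control 4, 6 were higher and the adjusted p with an estimated correlation was 0.0076.

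Of 8 lymphocyte and platelet miRNAs, 1, miR-146a-5p, was higher, 0 lower and 7 not called, also adjusted over the list alone (camera adjusted p = 0.00232; adjusted p = 0.0443 with an estimated correlation). miR-150-5p was at 23.1 ± 24.1 CPM against 3.38 ± 4.44, with 70.2 CPM in coculture 4. Of 11 NF-kB responsive miRNAs, miR-146a-5p and miR-146b-5p were higher, 0 lower and 9 not called, also adjusted over the list alone, and the camera adjusted p of 9.63e-05 became an adjusted p of 0.208 with an estimated correlation. miR-155-5p, which NF-kB and AP-1 induce, was at 3110 ± 393 CPM against 2293 ± 571 (edgeR adjusted p = 0.32). Of 18 miRNAs of papillary thyroid cancer, 2, the miR-146b arms, were higher, 0 lower and 16 not called, also adjusted over the list alone (camera adjusted p = 0.21). miR-21-5p was at 427004 ± 38906 CPM against 386144 ± 40702 and miR-181a-5p at 2714 ± 232 against 3339 ± 510, neither called. The let-7 family had 9 tested members, the miR-17-92 cluster and its paralogs 16, hypoxia miRNAs 7 and p53 responsive miRNAs 9, with 0 called in each, also adjusted over the list alone. Camera adjusted p-values were 0.315, 0.182, 0.967 and 0.47 in that order. For the miR-17-92 list the median of 0.12 and the mean of -0.08 differed in sign, and without control 4 its camera adjusted p was 0.0146, with an adjusted p of 0.316 by an estimated correlation. In the hypoxia list camera and fry gave opposite directions, and the p53 list, lower on balance, had an adjusted p of 0.035 by fry. In all, 5 of 10 miRNA lists passed camera, 2 passed with an estimated correlation and 3 passed fry.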

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

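Of the tests of explanations given here, that of transcript length was set before its result was seen, and those of miR-486-3p, of the leukocyte genes and of a state shared across assays were chosen after the result was seen. In 224 groups of 4 or 6 libraries, 35 had 1 library whose gap to the nearest other, as a share of the group's range, was above Dixon's critical value at 95%, where chance alone marks about 1 in 20 groups.

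Control 4 of the miRNA assay stood apart, high, for 10 miRNAs. The shares were 0.977 for miR-486-3p, 0.972 for miR-486-5p, 0.987 for miR-451a, 0.982 for miR-144-3p, 0.98 for miR-144-5p, 0.936 for miR-223-5p, 0.928 for miR-150-5p, 0.999 for miR-223-3p, 0.977 for miR-142-3p and 0.991 for miR-142-5p. In this library miR-486-3p was 11.2 times and miR-451a 23.4 times the mean of controls 1 to 3.

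For the lower miR-486-3p in coculture, blood RNA in control 4 as the whole reason was not settled. Without that library the value was -0.66 ± 0.27 on the log2 scale, 2.45 SE below 0, but the edgeR adjusted p was 0.745. The ranges overlapped, with controls 1 to 3 from 78.2 CPM and coculture up to 84.8 CPM. Red cell small RNA whose amount varies between libraries is a candidate explanation of what remains: over the 6 coculture libraries log2 CPM of miR-486-3p and miR-451a had r = 0.947 (exact permutation p = 0.00694, 0.0104 after Benjamini-Hochberg adjustment), rho = 0.943 (exact permutation p = 0.0167) and r = 0.871 without the 2 libraries farthest from the median. The adjustment is over the 3 such correlations across libraries tested. A change of miR-486 itself cannot be told apart from it, since the log2 ratio of miR-486-3p to miR-451a differed by 0.13 ± 0.17 (SE) between coculture and controls 1 to 3 (exact permutation p = 0.643) and 3 controls leave a wide interval. That log2 ratio was -4.48 in control 4, with means of -3.42 ± 0.04 (SD) in controls 1 to 3 and -3.29 ± 0.41 (SD) in coculture. The 2 miRNAs thus did not keep the proportion of control 4 in the other libraries. Which of these explanations holds was not settled by any value here.

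For the leukocyte genes in coculture, RNA of neutrophil-type cells with their usual transcripts was neither shown nor excluded. The summed CPM of S100A8, S100A9, FCGR3B, CSF3R, CXCR1 and CXCR2 was at most 0.145 of that of LYZ (mean 0.0827, SD 0.0342), with 0 counts of FCGR3B, CXCR1 and CXCR2. A first limit of 0.1 was passed by 1 library. With the ratios known, the limit was then restated as lying below LYZ by more than 2 SD in every library. The restated limit takes such cells to hold at least as much of these 6 genes as of LYZ. No table holds that profile, so the test cannot decide. RNA of the added cells in another state may also account for the leukocyte genes. In every coculture library 4 of 4 miRNAs of blood cells (miR-223-3p, miR-142-3p, miR-142-5p and miR-150-5p) were higher than in controls 1 to 3. Control 4, which had no added cells, was high in them too. These miRNAs do not tell such a state from the usual one. Leukocyte RNA as the whole rise of the NF-kB genes was not settled. The summed CPM gain of all 27 called leukocyte genes was at most 0.0839 of that of 18 called NF-kB genes in any coculture library (mean 0.0565, SD 0.0176). LYZ was at 13.9, CD53 at 1.68 and TYROBP at 1.18 CPM beside a summed NF-kB gain of 1559 CPM. In that gain NFKB2 went from 99.4 to 199 CPM and RELB from 43.6 to 99.3. The limit for this ratio was set after the correlation of the gains given below had settled nothing. It takes leukocytes to bring their own abundant transcripts along. No table holds the profile of the added cells, so the ratio cannot decide. Leukocyte genes that were not called, such as G0S2 with its high level in controls, are not in that sum. Leukocyte RNA as the whole or a part of the rise and a response of the TPC-1 cells stay open. The gains of the NF-kB genes and of 21 leukocyte genes under 0.5 CPM in controls had r = 0.467 (exact permutation p = 0.351, also after adjustment), rho = 0.6 (exact permutation p = 0.242) and r = 0.52 without the 2 farthest of 6 libraries.

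In the RNA-seq values coculture 1 and 2 stood apart on the first component, and of the splits drawn at random 1, coculture 1, 2 and 5 with control 1 against the rest, called 855 genes. For the calls of that split, transcript length bias is argued against. The Spearman rho across 15626 genes between its fold change and length was 0.0554, where genes are not independent replicates. For coculture minus control the rho with length was -0.177. Coculture 1 and 2 alone were not compared with length. A state of the cells or RNA that libraries of one number share in both assays is a candidate explanation, since the first components of both assays, centred within groups, had r = 0.724 over 10 numbers (exact permutation p = 0.00081, 0.00243 after adjustment), rho = 0.636 (exact permutation p = 0.00619) and r = 0.71 without the 2 farthest. What that state is was not tested.

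Other libraries stood apart as follows. Coculture 4 was high for CXCL8 (0.657), CD74 (0.665), MMP1 (0.649) and miR-150-5p (0.739). Coculture 1 was high for COL1A1 (0.937) and LUM (0.694), and coculture 2 for miR-200c-3p (0.816), miR-141-3p (0.716) and the total count of RNA-seq (0.634). Low values were those of coculture 2 for LYZ (0.646) and CD53 (0.953), and of coculture 6 for the total count of miRNA-seq (0.655). Among RNA-seq controls, number 1 was high for SOX9 (0.97), EGR2 (0.947), SRGN (0.842) and TNFRSF13C (0.847), number 2 for COL6A1 (0.839) and CLDN1 (0.944), and number 4 for LYZ (0.958), while control 2 was low for NOV (0.846) and control 1 for ITGAM (0.914). A lone count set the value of 1 for CXCL5 and HLA-DRA in control 2 and for S100A9 in control 1. In miRNA-seq, control 1 was high for miR-21-5p (0.894).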

How the results depend on the processing

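The settings without coculture 1 and 2, with numbers 1 to 4 and a batch term, and with coculture 1, 2 and 5 and control 1 as a batch term were chosen only after the result was seen, and the others were planned. NFKB2 stayed called in all 22 settings, with log2 fold changes from 0.77 to 1.08, and miR-486-3p was called in none of the 20 in which it had a test, with values from -2.85 to -0.66. DESeq2 gave miR-486-3p no p-value and a log2 fold change of -2.49 ± 0.76, so it is not counted there. Scaling moved the median of all features by less than 0.1 on the log2 scale. With at least 40237801 counts, 3 counts of an RNA-seq library come to about 0.07 CPM, and a value below that rests on fewer counts.

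The 178 genes higher in coculture were 333 with DESeq2 and 303 with numbers 1 to 4, and 112 to 204 when 1 library was left out. The 29 lower were 106 with DESeq2, 112 without coculture 1 and 2, 122 with numbers 1 to 4, 48 with the second batch term, and 4 to 36 when 1 library was left out. Higher miRNAs went from 9 to between 5 and 12 on leaving out 1 library and lower ones from 1 to 0 or 1. The 1 lower miRNA became 0 with RLE, upper quartile, library size alone, the strict filter, limma-voom and robust fitting off, and in 16 of 21 settings in all, with 18 to 64 miRNAs lower at an unadjusted p under 0.05. It became 4 without a filter and 3 with DESeq2. Camera lists went from 19 to 7 for mRNA and from 5 to 2 for miRNA with an estimated correlation, to 10 and 3 with fry, and for mRNA to 11 without coculture 1 and 2. Fewer libraries enter the fits that leave some out, and fewer inform the contrast with the replicate block. For the other changes the cause was not tested.

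Whether the replicate numbers pair the samples was not settled, and the main fits used no block. Deviations from the group means of same-numbered libraries correlated at 0.35, -0.0825, 0.20 and 0.14 in RNA-seq. In miRNA-seq they correlated at 0.37, -0.0343, 0.21 and 0.36. Not every sample correlated best with its own number, which does not exclude a pairing. The replicate block gave 100 higher genes, 83 of them among the 178, and 10 lower, 3 of them among the 29. It gave 9 higher and 0 lower miRNAs, a LAPTM5 log2 fold change of 0.0442, one of 1.08 for miR-142-5p and one of -1.24 for miR-486-3p. It ended the calls of IL6, TYROBP, CD52, MRC1, CSF1R, IL7R, MX1, SERPINB2, CLDN1, COL6A2, DUSP1, EGR2, SESN1, BTG2, miR-200a-5p, miR-152-5p, miR-146b-3p and, of the 12 largest falls, all but FLG, SERINC2 and SOX9.

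Signs reversed for genes and miRNAs not past the threshold and for 3 medians of lists past the camera threshold, and the cause was not tested. In the main fit these medians were 0.36 for hypoxia, 0.25 for MAPK and -0.08 for G2/M. On leaving out 1 library, the LAPTM5 log2 fold change ran from -0.0725 to 0.0303, SPARC from -0.0496 to 0.15, BANK1 from -0.0664 to 0.19, TNFRSF13C from -0.31 to 0.0910, MYL9 from -0.0795 to 0.0894, LUM from -0.39 to 0.57 and miR-142-5p from -0.80 to 2.27. Without coculture 1 and 2, the SPARC log2 fold change was -0.16, that of EGFL7 -0.0259, of LUM -0.82, the G2/M median 0.0268, the hypoxia median -0.0116 and the MAPK median -0.0028. With numbers 1 to 4, LAPTM5 was at 0.0413 and miR-142-5p at 0.47. With the second batch term, SPARC was at -0.0717, LUM at -0.14 and miR-142-5p at 0.18. MYL9 was at 0.0118 with upper quartile scaling and at 0.00357 with the strict filter, and limma-voom gave LUM -0.0528 and miR-142-5p 0.92. Of the genes, miRNAs and lists past the threshold, these 3 medians were those that changed sign in any setting. The planned search for miR-486-3p sites, with both its alternatives, was not run.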

Other observations

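The test of strands given here was chosen after the result was seen, while the splits of the libraries were planned. miR-486-3p and miR-486-5p had nearly equal counts, 8867 and 8778 in all, with a ratio of 0.932 to 1.13 in each library, although the arms of a hairpin seldom have equal counts. Hairpins are annotated on both strands of that place, so counting that does not separate strands could make the arms alike. Among pairs of miRNAs, this one included, that were reverse complements over 16 bases and had at least 100 counts in the larger member, 40.5% of 74 were within 1.5-fold, against 4.66% of 343 ordinary arm pairs. As 48 of the 74 share a member with another pair, they are not independent, and no p-value is given. The share was higher among such pairs, but the mark set for such counting, more than 50%, was not reached. This test therefore did not decide between the 2 readings. The 74 pairs mixed arms of a single hairpin, such as miR-5588-3p and miR-5588-5p, with miRNAs of different hairpins, which were not looked at apart.

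Refits on 100 of the 210 splits of 10 libraries into 6 and 4, the real split included, bear on chance. Fewer than 5% of the drawn splits gave as many for the 178 genes higher in coculture (highest other split 269) and the 29 lower (586). The same held for the 9 miRNAs higher (16) and the 5 miRNA lists (6). In 2, 2, 2 and 4 of the splits the number was as large. Chance cannot be excluded for the 19 mRNA lists, matched in 11 splits (highest other 21, median of the others 11). Nor can it for the 1 miRNA lower (19), matched in 5. For the other counts these shares do not exclude chance either. The shares take the libraries as independent and interchangeable, which was not established, and not all splits were drawn. For the NF-kB, cytokine, neutrophil, monocyte, pan-leukocyte and miR-200 lists the real split alone of the 100 gave a camera p as small. The same held for the lymphocyte and platelet miRNAs and for the NF-kB responsive miRNAs. With the real split included, 24 splits gave a camera p as small for the interferon list, 68 for G2/M and 62 for ribosomal proteins. The number was 37 each for hypoxia, heat shock and cholesterol, 29 for erythroid miRNAs and 27 for G1/S. It was 16 for histones, 15 for MAPK, 8 for myeloid miRNAs and 7 for p53. For antigen presentation and papillary thyroid cancer genes it was 5, for JAK-STAT3 targets 4 and for matrix proteases 2. The camera threshold itself was passed often: by the NF-kB list in 65 of the 100 splits, cytokines in 57 and pan-leukocyte genes in 56. The neutrophil list passed in 45, miR-200 in 36, monocyte markers in 35, NF-kB responsive miRNAs in 25 and lymphocyte and platelet miRNAs in 3. The smallest camera p of the NF-kB list in another split was 9.65e-43, so very small camera p-values also arose under other groupings. A split that calls several times the real number points to a structure of the samples. The split of coculture 1, 2 and 5 with control 1 against the rest called 855 genes and 35 miRNAs, and with it as a batch term, an alternative chosen after seeing the data, 200 genes were higher and 48 lower, the NFKB2 log2 fold change was 0.92 and the miR-486-3p log2 fold change was -2.22.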
